A study of Canis lupus familiaris with 37 samples.

How the data were processed

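The series compared mammary tissue of dogs in 3 groups. The labels name 8 samples of normal gland, 8 of hyperplasia induced with progesterone (CMH) and 21 of spontaneous mammary tumours (CMC). Each of the 37 samples was hybridised to its own spotted cDNA array, a glass slide carrying cloned canine cDNA fragments, together with a pooled reference. Per the labels, total RNA was amplified to cRNA by in vitro transcription and coupled to Cy3 or Cy5, and the reference held an equal amount of cRNA of every sample. Replicate numbers are those in the labels. The labels give each sample its own number within its group and do not name the dogs, so p-values measure the spread between these arrays. The design text gives equal numbers of both dyes per group, whereas the sample labels put the sample in Cy5 on 5 of 8 normal, 4 of 8 CMH and 11 of 21 CMC arrays; the sample labels were followed.

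The deposited scanner tables hold, per the file headers, the mean intensity and the mean and SD of the local background of each spot in Cy3 and in Cy5, on a linear scale, with scanner flags. The deposited tables also carry print-tip normalized log2 ratios of Cy5 over Cy3 made by the authors. The values matched those of the series matrix on 100% of the spots of every array, within 0.001, after each ratio had been turned to sample over reference. The matrix therefore holds log2 ratios of the authors, and its column medians lay between -0.026 and 0.028. Scale, centring and direction of the matrix were settled in this way. The scanner and its software version are not given in the sources used here.

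Each array held 22176 spots in 48 blocks, of which 20313 carried 20160 different clones and 1863 were control or empty spots. The files identify clones by library codes, and neither the files nor the gene table supplied for the dog pair these codes with gene names (0 clones matched). The 29 gene lists fixed in advance could therefore not be tested, and clones are given by code. A code constant over arrays marked some clones as unusable, and 33 of the 37 files combine this code with the scanner flags in 1 overall flag; for the other 4 files the same flag was rebuilt from its parts. Flagged spots were treated as missing.

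Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3. Each array was then normalized with 1 loess curve over its clone spots. Ratios were turned to sample over reference by the dye in the labels, and spots of 1 clone were averaged. A clone was tested if the channel of the sample exceeded its local background by 2 background SDs on at least 8 of the 37 arrays and if it had at least 4 values in each group. This left 18425 clones; 1412 were removed by flags and codes and 323 by the background rule. Over the arrays, 90.7 to 97.8% of clone spots exceeded background in the channel of the sample, and the median signal over background lay between 1.82 and 4.16. The number of arrays limits the precision.

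All 37 arrays entered 1 linear model (limma lmFit and eBayes) with 3 group means and a term for the dye of the sample, and clones were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The model shares 1 spread per clone over the 3 groups. Where a clone varied more in a small group than elsewhere, its SE and p-value can therefore be too small. Group levels are dye-adjusted log2 ratios against the reference pool. With no gene names, the rule for named items, read as applying to both directions, gave the 2 called clones with the largest rise and the 2 with the largest fall per comparison, among those whose difference had the same sign in Cy5 and in Cy3 arrays, a condition carried over from the rule for named genes. The spread within groups was the root mean square deviation of an array from its group mean over clones after removal of the dye term, scaled for the size of the group, compared with 2-sided permutation tests, exact where both groups had fewer than 10 arrays and with 100000 resamples otherwise. These choices, the alternatives and the rule were fixed before the data were examined, except where stated.

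The arrays fell into 2 sets that were taken as print runs of the slides. No label gives a print run, and the sets were inferred from the reference channel alone: 931 spots were lit on 98.3 to 100% of occasions on 21 arrays (the full run) and on 0.215 to 1.40% on the other 16 (the partial run). The arrays were first divided by their share of clone spots above background in the reference channel. The 931 spots were then chosen as lit on over 90% of 1 set and under 10% of the other. This contrast therefore partly follows from the choice of spots. The full run held 6 normal, 2 CMH and 13 CMC arrays and the partial run 2 normal, 6 CMH and 8 CMC arrays. No CMH array of the full run had its sample in Cy5, and no normal array of the partial run had its sample in Cy3. Of the tested clones, 826 had such a spot and are called dark clones below. Their reference signal did not exceed background on most arrays of the partial run, which held 6 of the 8 CMH arrays. Every count was refitted with the run as a block and within each run. The dye term passed the threshold for 9619 clones (52.2%) and the run term for 8.

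Tissue codes T18 and T18d differ by a letter whose meaning is not stated. By the rule fixed in advance, the arrays would have been averaged if their log ratios had correlated higher than every other pair of tumour arrays by over 0.1. Their correlation over clones was 0.14 against 0.76 for the highest other pair, so they were kept apart. The arrays have opposite dyes, which can lower this value, so the rule was a weak test of a repeated tumour. After removal of group, dye and run together it was 0.67, rank 2 of 210 tumour pairs, whose median was 0.0045. The effect of dye alone was not separated. If both arrays carry 1 tumour, every count of tumours holds it on 2 arrays. The fit with both averaged is among the alternatives. Same-numbered arrays of different groups deviated from their group means with correlations over clones from -0.12 to 0.34 for normal and CMH, -0.32 to 0.04 for normal and CMC, and -0.22 to 0.24 for CMH and CMC, so the numbers were not taken to pair samples.

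The fit was tested on simulated data for all 18425 clones, with the spread of each clone in each group as measured and 200 clones changed. A log2 change of 0.5 was recovered for 46 of 67 clones (68.7%) in CMH against normal and for 54 of 67 (80.6%) in each of the other comparisons. A log2 change of 1 was recovered for 65, 66 and 67 of 67 clones in CMH against normal, CMC against normal and CMC against CMH. Of the simulated calls, 9.23%, 6.53% and 8.78% were false in the same order. The simulated noise was independent between clones and arrays, unlike the measured ratios, whose first principal component held 31.9% of the variance. These rates therefore need not hold for the data.

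Alternatives covered background correction, normalization, filters, flags, the dye term, the arrays in the fit, replicate number, array weights, the variance model, the series matrix, thresholds, a SAM-style permutation test in place of limma, and each of the 37 arrays left out in turn. Set tests and averaging of probes per gene were not run, since no clone had a gene name.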

Results

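Expression was measured on 37 two-colour cDNA arrays of canine mammary tissue, each sample against the pooled reference. The arrays comprised 8 of normal gland, 8 of progesterone-induced hyperplasia (CMH) and 21 of spontaneous tumour (CMC). On the median array 97.1% of clone spots exceeded background in the channel of the sample. The design asked which transcripts differed from normal gland in each lesion. The groups also imply a direct comparison of the lesions.

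In hyperplasia, clone DG2-100m16 showed the largest rise among called clones. Its dye-adjusted log2 ratio to the reference was 0.31 ± 1.73 (SD, n = 8) in CMH and -2.03 ± 0.73 (SD, n = 8) in normal gland, a log2 difference of 2.34 (SE 0.46, limma adjusted p = 0.0288). All 8 CMH arrays lay above the mean of the normal arrays, but they ranged from -1.86 to 2.88. Clone DG2-24a6 was at 0.28 ± 0.24 (SD, n = 8) in CMH against -0.41 ± 0.32 (SD, n = 8) in normal gland, a log2 difference of 0.69 (SE 0.13, limma adjusted p = 0.0288). Among called clones with the same sign in both dyes, DG2-63k4 and DG2-72i20 fell most. DG2-63k4 was at -1.33 ± 0.87 (SD, n = 8) in CMH and 0.60 ± 1.09 (SD, n = 8) in normal gland, and DG2-72i20 at -0.61 ± 0.45 (SD, n = 8) and 0.85 ± 0.52 (SD, n = 8). Their log2 differences were -1.93 (SE 0.40, limma adjusted p = 0.0302) and -1.46 (SE 0.29, limma adjusted p = 0.0288). All 8 CMH arrays lay below the normal mean for both clones. DG8-46n19 and DG32-8o18 had log2 differences of -2.01 and -1.85 between CMH and normal gland but were not called (limma adjusted p = 0.163 and 0.153).

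Across the array, 7 clones were higher and 17 lower in CMH than in normal gland, with a median log2 change of 0.57 for the rises and -0.85 for the falls. The unadjusted p was under 0.05 for 2379 clones, where 921 would be expected by chance. The numbers changed with the arrays fitted: 197 clones were higher and 428 lower when only the CMH and normal arrays were fitted (1 and 20 with the inferred print run as a block), and 211 higher and 574 lower without 5 tumours that stood apart from all other arrays (92 and 438 with the block). Leaving out these tumours and the run as a block were settings chosen after the data were seen. With print-tip loess the split was 17 higher and 26 lower (39.5% higher against 29.2%). With the inferred print run as a block, 4 clones were higher and 16 lower, of which 15 were called without it; DG2-100m16 then had a log2 difference of 2.13 and an adjusted p of 0.0681 in limma (0.00784 to 0.767 over its 8 refits with other settings). Within the full run, limma called 1 clone higher and 0 lower (1270 at an unadjusted p under 0.05), and within the partial run 0 clones (937 at an unadjusted p under 0.05), with only 2 arrays in 1 of the groups each time. Refitted within the full and partial run, the log2 differences of DG2-100m16 were 2.74 and 2.04, those of DG2-24a6 were 1.01 and 0.62, those of DG2-63k4 were -2.18 and -2.85, and those of DG2-72i20 were -1.75 and -1.17. Limma called 0 clones when any 1 of normal replicates 4, 5, 6 and 7 or CMH replicates 1 and 3 was left out (1915 to 2082 clones at an unadjusted p under 0.05), so none of the 4 named clones was called there. It called 1 and 9 clones without CMH replicates 8 and 6, 161 without normal replicate 8, and 121 and 37 without CMC replicates 8 and 11. The larger share turned to rises without normal replicate 1 (131 higher, 74 lower), without CMH replicate 4 (27 higher, 18 lower) and with array weights (1327 higher, 1135 lower). A SAM-style permutation test of the CMH and normal arrays, which has no dye term, gave 288 higher and 310 lower.

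In spontaneous tumours, DG2-28a22 and DG33-72n16 showed the largest rises against normal gland among called clones with the same sign in both dyes. DG2-28a22 was at 0.48 ± 0.97 (SD, n = 21) in CMC and -1.62 ± 0.40 (SD, n = 8) in normal gland, a log2 difference of 2.11 (SE 0.34, limma adjusted p = 0.000328), and 20 of 21 tumours lay above the normal mean. DG33-72n16 was at 0.26 ± 1.18 (SD, n = 21) and -1.53 ± 0.48 (SD, n = 8), a log2 difference of 1.79 (SE 0.40, limma adjusted p = 0.00578), again with 20 of 21 tumours above the normal mean. The deepest falls among such clones were those of DG8-46n19 and DG32-8o18, by 2.76 (SE 0.55, limma adjusted p = 0.00225) and 2.60 (SE 0.50, limma adjusted p = 0.00170) on the log2 scale. Both were uniformly low in tumours, at -3.00 ± 0.54 and -2.87 ± 0.46 (SD, n = 21), and uneven in normal gland, where DG8-46n19 ranged from -3.15 to 3.75 and DG32-8o18 from -2.92 to 3.36. The SDs in normal gland were 2.53 for DG8-46n19 and 2.30 for DG32-8o18 (n = 8). The SEs above come from a spread shared with the uniform tumours and understate this, so the adjusted p-values are too small. All 21 tumours lay below the normal mean for both. The log2 differences were -4.05 among Cy5 and -0.75 among Cy3 arrays for DG8-46n19, and -3.81 and -0.70 for DG32-8o18.

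Over all clones, 521 were higher and 425 lower in CMC than in normal gland, 5.13% of those tested, mostly by small amounts: the median rise was 0.35 and the median fall -0.41 on the log2 scale, and 21 rises and 50 falls reached 2-fold. With the print run as a block the counts were 487 and 452, and 871 of the 946 called clones were called in both fits. Within the full run 99 clones were higher and 95 lower; within the partial run, with 2 normal arrays, 1 was higher and 0 lower in limma (1166 clones at an unadjusted p under 0.05). The SAM-style test gave 497 higher and 475 lower. Refitted within the full and partial run, the log2 differences were 2.20 and 1.55 for DG2-28a22, 1.71 and 1.57 for DG33-72n16, -2.47 and -4.35 for DG8-46n19, and -2.35 and -4.08 for DG32-8o18. The total fell to 557, 626, 491 and 476 clones without normal replicates 3, 4, 5 and 7 respectively. Falls outnumbered rises without normal replicate 3 (278 higher, 279 lower) and 5 (234 higher, 257 lower), with median centring (298 higher, 328 lower) and among Cy5 arrays (55 higher, 87 lower). Without the 5 tumours that stood apart, a setting chosen after the data were seen, 607 clones were higher and 699 lower.

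The lesions were also compared directly. Among called clones with the same sign in both dyes, DG2-10p3 and DG11-224l18 rose most in CMC against CMH. DG2-100m16 and a clone of library DG31 fell most. The DG31 clone lies in block row 8 and block column 4, at spot row 3 and spot column 5, and its full code heads its panel in the plot of named clones. DG2-10p3 was at 0.37 ± 1.28 (SD, n = 21) in CMC and -1.97 ± 1.39 (SD, n = 8) in CMH, a log2 difference of 2.34 (SE 0.50, limma adjusted p = 0.00935). DG11-224l18 was at 0.33 ± 1.23 (SD, n = 21) and -1.82 ± 1.26 (SD, n = 8), a log2 difference of 2.15 (SE 0.47, limma adjusted p = 0.0111). For each, 20 of 21 tumours lay above the CMH mean. DG2-100m16, the called clone with the largest rise in hyperplasia, was at -1.99 ± 0.53 (SD, n = 21) in CMC, a log2 difference from CMH of -2.30 (SE 0.38, limma adjusted p = 0.00206). The SD of DG2-100m16 in CMH was 1.73 (n = 8), which this shared SE understates. Its log2 difference between CMC and normal gland was 0.04 (SE 0.39, limma adjusted p = 0.955). The DG31 clone was at -1.49 ± 1.01 (SD, n = 21) in CMC and 0.18 ± 1.16 (SD, n = 8) in CMH, a log2 difference of -1.66 (SE 0.44, limma adjusted p = 0.0409), with 19 of 21 tumours below the CMH mean. With the print run as a block its log2 difference was -1.32 and its adjusted p 0.112 in limma (0.0334 to 0.894 over its 8 refits with other settings), and it also missed the threshold without any 1 of 12 arrays.

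In total 85 clones were higher and 215 lower in CMC than in CMH. With the print run as a block, 84 were higher and 138 lower, and 188 of the 300 called clones were called in both fits. Within the full run, with 2 CMH arrays, limma called 0 higher and 1 lower (885 clones at an unadjusted p under 0.05), and within the partial run 88 higher and 108 lower. The SAM-style test gave 181 higher and 282 lower. Refitted within the full and partial run, the log2 differences were 1.95 and 2.65 for DG2-10p3, 1.95 and 2.31 for DG11-224l18, -2.86 and -1.72 for DG2-100m16, and -1.77 and -1.09 for the DG31 clone. The total fell to 138, 108, 144 and 151 clones without CMH replicates 1, 3, 6 and 8, and rose to 563 without CMH replicate 4 and to 481 without CMC replicate 20.

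**Figure D1:**
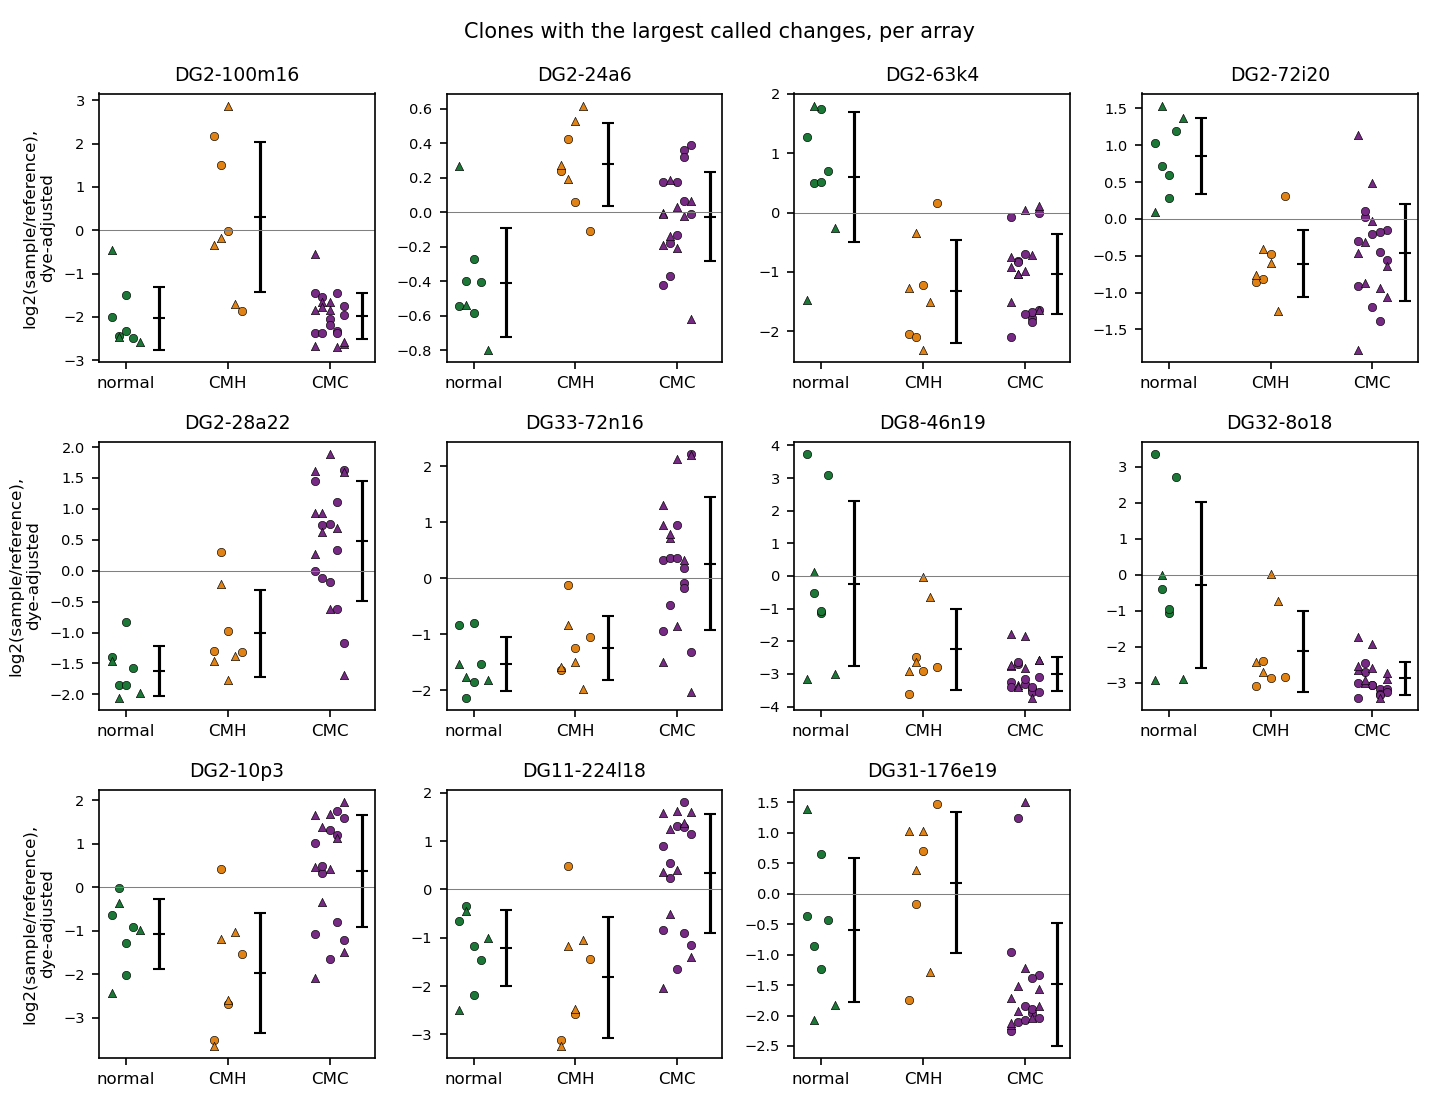
Dye-adjusted log2 ratio of sample to reference (vertical axis) for the 11 clones named for the 3 comparisons, by group; circles are arrays with the sample in Cy5, triangles arrays with the sample in Cy3, and bars show the mean ± SD (normal n = 8, CMH n = 8, CMC n = 21). DG2-100m16 reaches 2.88 in CMH while no CMC array exceeds -0.55, and DG8-46n19 spans -3.15 to 3.75 in normal gland.

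Some clones were called in both lesions. Of the clones called against normal gland, 3 were higher in both lesions, 14 were lower in both and 0 went in opposite directions by limma. Independent lists of these lengths would share 0.20 higher and 0.39 lower. Few if any opposite calls are to be expected from lists this short, so their absence carries little weight. DG2-63k4 and DG2-72i20, the clones named for their falls in CMH, were also lower in CMC, with log2 differences of -1.63 (SE 0.33, limma adjusted p = 0.00285) and -1.31 (SE 0.24, limma adjusted p = 0.00114). DG2-24a6 was higher in CMC by 0.38 (SE 0.11, limma adjusted p = 0.0361). Shared calls numbered 0 without any 1 of normal replicates 4, 5, 6 and 7 or CMH replicates 1 and 3, 1 and 8 without CMH replicates 8 and 6, 120 and 92 without normal replicates 1 and 8, and 43 without CMC replicate 8. They numbered 826 with array weights, 407 without the 5 tumours that stood apart (313 with the print run as a block) and 101 with each pair of groups fitted alone (4 with the block). Both comparisons used the same normal arrays. In the 70 splits that gave each lesion its own 4 normal arrays, the median number of shared calls was 0 in each direction and the highest was 1 higher and 5 lower. With only 4 normal arrays per lesion fewer calls are to be expected. These numbers therefore do not decide whether the overlap came from the shared arrays. Across clones, which are not independent replicates, the log2 changes correlated with r = 0.56. Unchanged groups simulated against the same normal arrays gave a mean r of 0.53 (-0.06 to 0.88 over 100 draws), and with the normal arrays split the median r was 0.38 (0.14 to 0.60). The covariance of the log2 changes was 0.0215 against a simulated mean of 0.00558, a difference of 0.0159, and above the highest of the 100 simulated draws, 0.0175. With the normal arrays split, its median was 0.0165 (0.00746 to 0.0215). Within the full run r was 0.38 and within the partial run 0.68.

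Tumour arrays differed more from one another than arrays of the other groups. The root mean square deviation from the group mean was 0.294 ± 0.0886 (SD, n = 21) in CMC, 0.203 ± 0.0184 (SD, n = 8) in normal gland and 0.179 ± 0.0456 (SD, n = 8) in CMH on the log2 scale. CMC exceeded normal gland by 0.0904 (permutation p = 0.00830, adjusted p = 0.0249 over 9 tests) and CMH by 0.115 (permutation p = 0.00183, adjusted p = 0.0165). The excess over CMH missed the threshold with plain background subtraction (0.0764, permutation p = 0.0620) and in the authors' ratios (0.0295, permutation p = 0.528). CMH and normal gland did not differ past the threshold (difference -0.0247, exact permutation p = 0.179), and the sign turned in the authors' ratios, where CMH was the more spread (0.110, exact permutation p = 0.0392), and with plain subtraction (0.0565, exact permutation p = 0.0513). With the print run as a block the excess of CMC was 0.0837 over normal gland (permutation p = 0.0121) and 0.104 over CMH (permutation p = 0.00367). Against normal gland it was 0.122 within the full run (permutation p = 0.00215) and -0.000233 within the partial run, which held 2 normal arrays (exact permutation p = 1). Against CMH it was 0.0873 (permutation p = 0.0956) in the full run, which held 2 CMH arrays, and 0.0788 (exact permutation p = 0.0153) in the partial run. CMH differed from normal gland by 0.0342 in the full run (exact permutation p = 0.0714) and by -0.0790 in the partial run (exact permutation p = 0.0357, the smallest that 2 against 6 arrays allow). The deviations of 2 arrays of the same dye from their mean are equal by construction, so tests against such a pair carry little weight. Without the 5 tumours that stood apart the excess over normal gland was 0.0255 (permutation p = 0.104), and leaving out the arrays farthest from the rest lowers the spread by construction. Without CMH replicate 4, CMH lay below normal gland by a difference of -0.0420 (exact permutation p = 0.0138). Clones over 2-fold from the normal mean numbered 519 ± 491 (SD, n = 21) in CMC, 130 ± 66.2 (SD, n = 8) in CMH and 88.0 ± 44.7 (SD, n = 8) in normal gland, each normal array being set against the other 7. CMC exceeded normal gland by 431 clones (permutation p = 0.0160, adjusted p = 0.0287), by 546 in the full and 233 in the partial run, and by 174 without the 5 tumours (permutation p = 6e-05). A change shared by all tumours raises this count. It therefore measures distance from normal gland and does not show that tumours differ from one another.

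**Figure D2:**
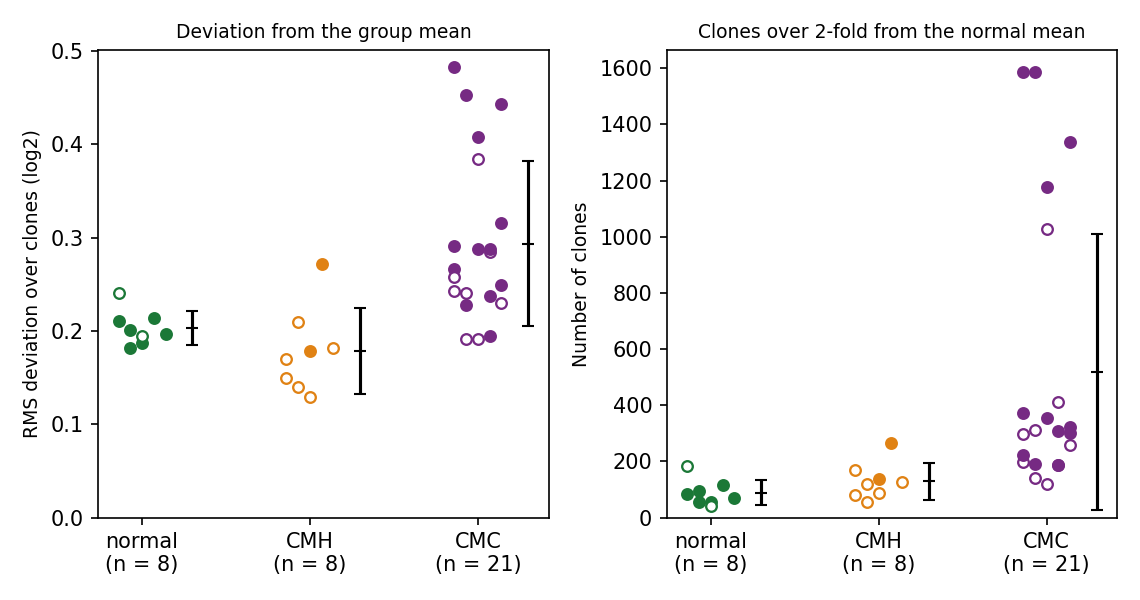
Root mean square deviation of each array from its group mean over clones (left, log2 units) and number of clones over 2-fold from the normal mean (right), by group; filled points are arrays of the full print run, open points arrays of the partial run, and bars show the mean ± SD. In CMC the deviation runs from 0.192 to 0.483, and 5 tumours have 1029 to 1587 clones over 2-fold from normal.

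The first principal component of the dye-adjusted ratios held 31.9% of the variance over 17922 clones. CMC replicates 2, 3, 8, 10 and 11 scored 56.5, 49.5, 43.8, 48.1 and 58.3 on it. The other 32 arrays, among them the remaining 16 tumours, scored at most 2.38, and normal and CMH arrays scored below 0 throughout. The second component held 9.88%.

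**Figure D3:**
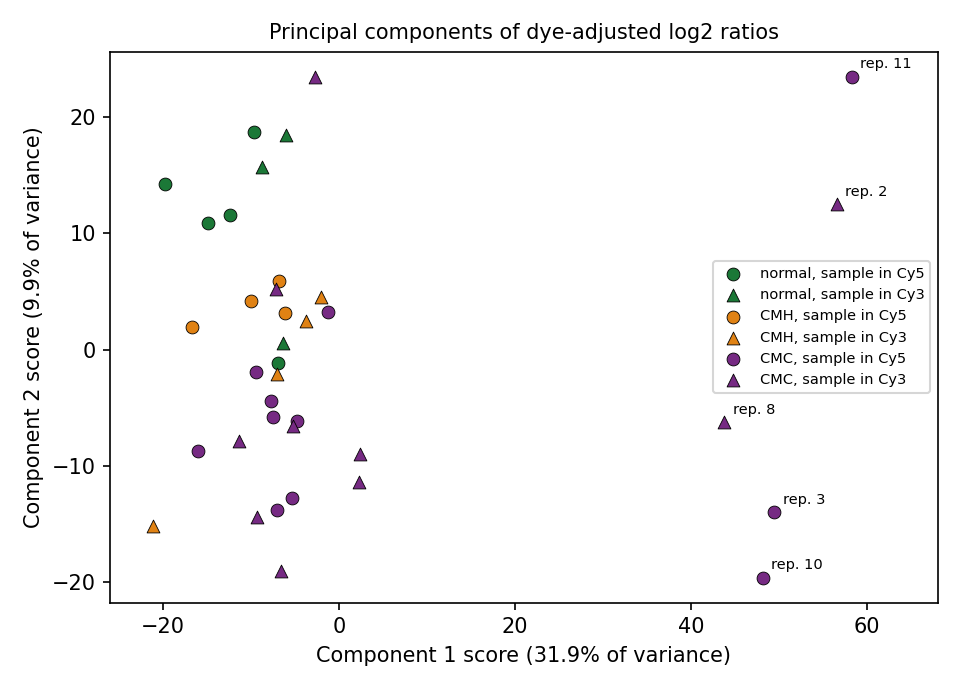
Scores of the 37 arrays on the first component (horizontal) and the second component (vertical) of dye-adjusted log2 ratios; colour gives the group and shape the dye of the sample. CMC replicates 2, 3, 8, 10 and 11 lie at 43.8 or higher on the first component and every other array at 2.38 or lower.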

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

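The tests of control spots and of dye, print run, brightness, tumours left out and shared spread below were chosen after the results they concern had been seen; those of normalization, position on the slide, bright clones and random splits were written before.

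Of the control spots, 2 kinds differed between CMH and normal gland after adjustment. Spots coded ECAA000001 were lower in CMH than in normal gland by -0.41 on the log2 scale (0.34 ± 0.14 in normal gland, -0.07 ± 0.24 in CMH, SD, n = 8 each, exact permutation p = 0.00140, adjusted p = 0.0231 over 33 tests). Spots coded ECAA000003 differed by -0.30 (exact permutation p = 0.00109, adjusted p = 0.0231). Between CMC and normal gland the differences were larger, -0.70 and -0.44, but uneven among tumours, and missed the threshold after adjustment (permutation p = 0.0137 and 0.00739, adjusted p = 0.113 and 0.0813). In CMC the ECAA000001 spots were at -0.36 ± 0.77 (SD, n = 21): CMC replicates 2, 3, 8, 10 and 11 lay between -1.80 and -1.38 and the other 16 tumours between -0.20 and 0.51. The same 5 were low in ECAA000003 (-1.01 to -0.77, others -0.16 to 0.31) and in ECAA000005 (-2.01 to -1.20, others -0.22 to 0.29), whose group differences missed the threshold. What these spots carry is not given in the sources used here. Of 28 sets of 8 normal or CMH values examined for a single distant array, 0 held one, where chance gives about 1 in 20.

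The 5 tumours that scored apart on the first component might reflect the slides or the processing. They included 3 arrays with the sample in Cy5 and 2 in Cy3, and 4 of the full and 1 of the partial set that was taken as a print run, so neither dye orientation nor print run of the slide separates them. They scored above every other array in 5 of 5 other ratio sets, the authors' among them, and by 39.4 units in the brighter part of the clones, which argues against normalization and dim clones as the whole cause; the 500 clones of largest weight were spread over 48 blocks with at most 3.6% in 1 of them. Weak labelling of the sample channel stays open: within their inferred print run, 4 of the 5 had a lower ratio of sample to reference signal over background than every other array, 0.726 to 0.835, whereas CMC replicate 8 had 9 of 15 others below its ratio of 0.974. The margin of CMC replicate 3 was very narrow. Its sample and reference signals over background were 2.88 and 3.45, those of CMC replicate 18, outside the 5, 2.94 and 3.51. On the same 5 arrays 3 of the 9 kinds of ECAA control spots were low throughout and the other 6 were not. ECAA000004 and ECAA000008 were higher on 4 of the 5 (0.11 to 0.19 and 0.17 to 0.20) than on the arrays outside the 5 (at most 0.07 and 0.12), so the controls did not fall together, and what they say about sample or labelling stays open. RNA quality, another tissue in the sample and a tumour type that the labels do not name were not tested, since clones lack gene names.

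Of 100 splits of the 16 CMH and normal arrays, 1, the real one, gave as many as 24 called clones, and the highest other gave 0. This makes a random grouping an unlikely source of the count. The splits did not hold the inferred print run as it lay in the real groups, so they do not separate group from run. The count also fell to 0 when some single arrays were left out. The print run of the slide might account for the calls, since most CMH arrays are of the partial run. With it as a block 15 of 24 clones were called again, and the median change of the 24 was 1.05 of its former size. In the fit of all arrays this argues against the run as the whole cause. In the fit of CMH and normal arrays alone, however, the run as a block took the calls from 197 higher and 428 lower to 21. How far the calls rest on the run therefore stays open. Whether tumour arrays widening the shared spread hold the count down cannot be told apart from other causes: CMH and normal arrays alone gave 21 clones with run and dye as terms and 197 higher and 428 lower with dye alone, whereas all arrays but the 5 tumours gave 530 with run and dye. Hormone treatment itself stays open as the biological difference that the design names.

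Of 100 splits of the CMC and normal arrays, 2 gave as many as 946 clones, the real one included, and the highest other gave 3431. Of 100 splits of the CMC and CMH arrays, 3 gave as many as 300, and the highest other gave 3945. Random groupings rarely gave as many calls, but those that did gave more than the real one, so chance is not excluded for either. The splits with 3431 and 3945 calls each put 4 of the 5 outlying tumours into the smaller group. Both comparisons used the same random draws, so these are 1 division of the tumours and not 2 separate cases. Another draw that put 4 of the 5 there gave 0 calls between CMC and normal gland and 2561 between CMC and CMH. Whether the place of these tumours produced the calls was not tested. The calls between CMC and normal gland might rest on the print run of the slide or on those 5 tumours, but 871 of 946 were called again with the run as a block and 772 of 946 without the 5 arrays. The difference between tumour and normal tissue stays open as a biological explanation.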

How the results depend on the processing

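Settings by print run, without the 5 outlying tumours and without dark clones were chosen after the data were seen. Counts are higher/lower for CMH against normal, CMC against normal and CMC against CMH, then shared calls; values within 1.5 times are left out. The cause of a change was not tested unless the setting leaves out arrays or raises the threshold.

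Without a dye term: 0/1, 319/257, 44/130, shared 1. Cy5 arrays: 0/0, 55/87, 0/3, shared 0. Cy3 arrays: 0 of each, with 1275, 1772 and 1186 clones at an unadjusted p under 0.05. Groups compared alone: 197/428, 321/254, 43 higher, shared 101; with the print run as a block 1 higher, 288/277, 40/83, shared 4, r = 0.41. All arrays with the run as a block: 4 higher in CMH, 138 lower in CMC than CMH. Full run: 1/0, 99/95, 0/1, shared 0, r = 0.38. Partial run: 0/0, 1/0, 108 lower, shared 0, r = 0.68. Median centring: 2/8, 298 higher, 56 higher, shared 7. Print-tip loess: 17/26. Plain subtraction: 130 higher in CMC than CMH. Series matrix: 13 higher in CMH than normal, 153 higher in CMC than CMH. Array weights: 1327/1135, 1194/836, 674/1014, shared 826. Trend and robust eBayes: 141 lower in CMC than CMH. SAM-style test: 288/310 and, for CMC against CMH, 181 higher. Adjusted p under 0.01: 0/0, 148/130, 19/74, shared 0. Adding a log2 change of 1: 1/7, 21/50, 11/10, shared 4. Larger scanner files left out: 30/78 in CMC against CMH. Dark clones left out: 12 higher in CMH, or 4 with the run as a block. Without the 5 tumours: 211/574, 699 lower in CMC than normal, shared 407; with the run as a block 92/438, 730, 127 lower in CMC than CMH, shared 313.

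With the replicate number as a block the counts were 0/0, 282 lower in CMC than normal and 108 lower in CMC than CMH, shared 0. The labels do not say whether the numbers pair samples, and they were not taken to do so.

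The spread of CMC over normal was -0.000233 within the partial run, 0.0255 without the 5 tumours and 0.0194 with the run as a block too. CMC over CMH was 0.0764 with plain subtraction, 0.0295 in the series matrix and 0.0873 in the full run (permutation p = 0.0620, 0.528 and 0.0956). CMH against normal was 0.110 in the series matrix (exact permutation p = 0.0392), opposite in sign to the -0.0247 reported, and -0.0790 in the partial run (exact permutation p = 0.0357).

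Leaving out 1 array at a time gave 0 to 131 higher and 0 to 84 lower for CMH against normal, 234 to 733 and 229 to 473 for CMC against normal, 28 to 199 and 80 to 421 for CMC against CMH, 0 to 120 shared calls and, for the spread of CMH against normal, -0.0420 to -0.0153.

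Aquantile leaves the ratios as they are and was no test. Filters on dim clones, flagged spots, no background correction and T18 with T18d averaged kept all counts within 1.5 times. The 11 named clones kept their sign in the 8 other settings in which they were refitted and with each array left out, though not always their call.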

Other observations

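The tests of clone libraries and clone pairs here were chosen after the data were seen; that of the reference pool was written before.

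Called clones were unevenly spread over the clone libraries whose codes open the clone names. Of 1457 tested clones of library DG14, 105 were lower in CMC than in normal gland (7.21%, against 1.89% of other clones, Fisher's exact test, adjusted p = 3.73e-25 over 40 tests). Of 3690 clones of DG2, 189 were higher (5.12% against 2.25%, adjusted p = 4.36e-17). Clones of each library lay in all 48 blocks, with at most 2.47% of DG14 in 1 block. Several clones can come from 1 transcript, so clones are not independent and these p-values are too small. The tissue behind each library is not given in the sources used here.

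All 55 pairs of the 11 named clones were correlated over the 16 tumours outside the separate set of 5, and 3 pairs passed an adjusted p of 0.05. DG2-10p3 and DG11-224l18 had Pearson's r = 0.991 and Spearman's rho = 0.982 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, adjusted p = 0.00055). DG8-46n19 and DG32-8o18 had r = 0.919 (permutation p = 2e-05, adjusted p = 0.00055) and rho = 0.809 (permutation p = 0.00033). DG2-28a22 and DG33-72n16 had r = 0.724 (permutation p = 0.0017, adjusted p = 0.0312), but rho = 0.647 did not pass (permutation p = 0.00817, adjusted p = 0.131). Without the 2 arrays farthest from the median, r was 0.984, 0.831 and 0.525 in the same order. The median r of the 55 pairs was 0.223. Each of these 3 pairs joined clones named for the same comparison and direction, though other such pairs did not pass. Without gene names it cannot be told whether the clones of a pair come from 1 transcript. They therefore need not be separate findings. Over all 21 tumours, which form separate sets, 5 pairs passed by Pearson's r: these 3 and the pairs of DG33-72n16 with DG2-10p3 and DG11-224l18. By Spearman's rho, DG33-72n16 with DG11-224l18 (permutation test, adjusted p = 0.096) and with DG2-28a22 (permutation test, adjusted p = 0.11) missed the threshold there.

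If the reference held an equal amount of each sample, the linear ratio of a clone to it should average 1 over the 37 arrays. For the 89 clones whose log2 ratio varied with an SD over 1, the median of this mean was 0.972 and single clones ran from 0.653 to 2.00. Loess centres the ratios of each array, and the median over all clones was 1.01, so this median does not decide whether the pool was equal.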
